A study of Arabidopsis thaliana with 2 samples.

How the data were processed

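The data were small RNA libraries from callus of Arabidopsis thaliana with an RKD2-GFP transgene, grown at 22 °C with 16 h of light, per the labels' protocols. Per the same protocols, extract with 3 mg of protein was incubated for 3 h with the bait in the affinity purification. An adenylated 3' adapter and a 5' RNA adapter were ligated in turn, and the amplified cDNA was size-selected on a gel around the miRNA band. The group of each library was taken from its label on affinity purification, with 1 library of total RNA (Input) and 1 of affinity-purified RNA (APP).

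The deposited sequence files give the read count of each distinct insert sequence as whole numbers, not normalized. CASAVA 1.8.2 is listed in the submitters' processing notes. Adapter trimming, any length filter and a genome build are not given in the sources used here, and the sequences ran from 18 to 45 nt. A deposited table gives, for each length from 18 to 28 nt, the count and the percent of the reads in that range, per the file headers. These deposited percent values leave out longer reads, so shares here were computed over all reads of a library, with the range of 18 to 28 nt as an alternative. Deposited counts without molecular identifiers include PCR copies. Reads that differ by 1 sequencing error count as distinct sequences, which raises the number of distinct and unmatched sequences.

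Each distinct sequence was matched without mismatches to both strands of the TAIR10.1 assembly, chromosomes 1 to 5, plastid and mitochondrion, and every match was kept. Sequences with an N, 0.0719% of Input reads and 0.0738% of APP reads, could not match. An exact match was found for 78.8% of Input reads and 86.2% of APP reads. A sequence took the first class that any of its matches lay wholly inside, in the order annotated rRNA, tRNA, snRNA or snoRNA, 25S rRNA region, 5S rRNA, MIR gene, TAS locus, other organellar, pseudogene, protein-coding gene, other non-coding gene and between genes. The annotation lists neither the nuclear 25S nor the 5S genes as rRNA. The 4000 bp downstream of each of 2 annotated 5.8S genes were therefore taken as the 25S region, and genome stretches covered by 24-nt windows of a 119-nt 5S sequence as 5S rRNA. Matches that overlap a structural gene only in part fall into later classes: 55.6% of Input reads and 0.585% of APP reads of the other organellar class shared at least 1 base with one. A set free of structural RNA was formed from matched reads that shared no base with annotated structural RNA, the 25S region or 5S rRNA, 18.3% of Input reads and 81.6% of APP reads. This set was formed after values for a first set had been seen, which left out only reads wholly inside structural RNA and so kept tRNA fragments that reach past the annotated gene. The closing part gives the values of both sets. Annotated pseudogenes rarely carry a description, and transposons were not annotated separately. Reads of a single locus were divided equally over all genome matches, and the intervals at loci treat the divided reads as counts. In the ratios of TAS loci by length, each read counted in full at every locus that it matched.

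Lists of 72 miRNA guides, 22 star strands, 3 trans-acting siRNAs and 6 TAS loci were written from memory before the data were examined and then checked against the genome and its annotation. Small RNAs were counted by exact sequence. Named small RNAs were, among those with at least 100 reads over both libraries, the 8 highest and 8 lowest log2 ratios and the 5 most abundant in each library, plus a fixed set of guides with a known Argonaute partner or role in siRNA production. The fixed name miR393b-3p was carried in the list by a sequence that the annotation names miR393a-3p, so the counts of both sequences are given. Named loci were the 4 highest and 4 lowest ratios among those with at least 1000 reads, MIR and TAS genes left out. Any small RNA or locus named outside these rules is said to be chosen after its values were seen.

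With 1 library per group there was no test between groups and no p-value. Shares have exact Clopper-Pearson intervals at 95%, rpm values exact Poisson intervals, and log2 ratios exact conditional binomial intervals, computed with SciPy 1.17.1 (Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, Numba 0.67.0). A count of 0 was taken to allow up to 3 counts, 1.14 rpm in Input and 0.883 rpm in APP. The matcher was tested on simulated data, where it found 400 of 400 planted sequences and matched 0 of 200 random ones. The ratios were tested on simulated data for APP over Input with 3903 sequences, of which 200 were changed by a log2 ratio of 2 in either direction. The median estimates were 2.05 for those raised and -1.98 for those lowered, 94.9% of the intervals held the simulated value, and 100% of the changed sequences had an interval on the right side of 0.

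Alternatives counted each distinct sequence once, left out the 10 most abundant sequences of either library, changed the denominator, added sequences with other 3' ends that shared the first 18 nt and were at most 26 nt long, divided reads over their matches, or lowered the minimum to 10 reads. Sequences without a genome match were searched for parts of cloning plasmids, the 5' RNA adapter and a list of mammalian miRNAs. The counts from this search enter only the closing part. The sequences searched for, and the 5S rRNA sequence behind the 5S class and the set free of structural RNA, were written from memory and not checked against a database. All 4 columns of the deposited table were used, and no column was left out.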

Results

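Small RNA libraries were compared from callus of Arabidopsis thaliana (Col-0) that carries an RKD2-GFP transgene. RKD2 is a plant transcription factor of the RWP-RK family, and cells that overexpress it grow as callus in culture. The Input library was made from total RNA. The APP library was made from RNA recovered by Argonaute protein affinity purification (Ago-APP), in which a GST-tagged fragment of the protein TNRC6B, residues 599 to 683, served as bait. TNRC6B belongs to the GW182 family, whose glycine-tryptophan motifs bind Argonaute proteins, and Argonautes are the proteins that carry small RNA guides. The series' stated purpose was to compare small RNA lengths between the 2 preparations. Each group held 1 library, so no difference had a replicate check and no test between groups was possible. Input held 2627492 reads of 557306 distinct sequences and APP held 3397527 reads of 487719 distinct sequences, all from 18 to 45 nt long. The libraries shared 50914 distinct sequences. Shares are given with exact (Clopper-Pearson) 95% binomial intervals, reads per 1000000 reads (rpm) with exact Poisson intervals, and log2 ratios of APP over Input with exact conditional intervals. Reads carried no molecular identifiers, so these intervals cover counting error of reads only and are too narrow where reads are PCR copies.

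APP was dominated by small RNAs of 24 nt, the length of the siRNAs that guide RNA-directed DNA methylation in plants. Reads of 24 nt made up 14.2% of Input (14.16 to 14.24%) and 70.3% of APP (70.27 to 70.37%), a 4.95-fold higher share in APP (log2 ratio 2.31, 2.30 to 2.31). Reads of 21 nt, the length of most plant miRNAs, took 10.96% of Input and 6.68% of APP (6.66 to 6.71%), a log2 ratio of -0.71 (-0.72 to -0.71). Of the other lengths that plant Dicer-like enzymes produce, 23 nt was higher in APP (7.32% and 8.61%), while 20 nt (6.97% and 3.36%) and 22 nt (6.60% and 5.13%) were lower. Reads outside 20 to 24 nt took 53.9% of Input and 5.90% of APP, a 9.14-fold lower share in APP (log2 ratio -3.19, -3.20 to -3.19). Reads longer than 28 nt accounted for 20.9% of Input and 0.377% of APP.

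**Figure D1:**
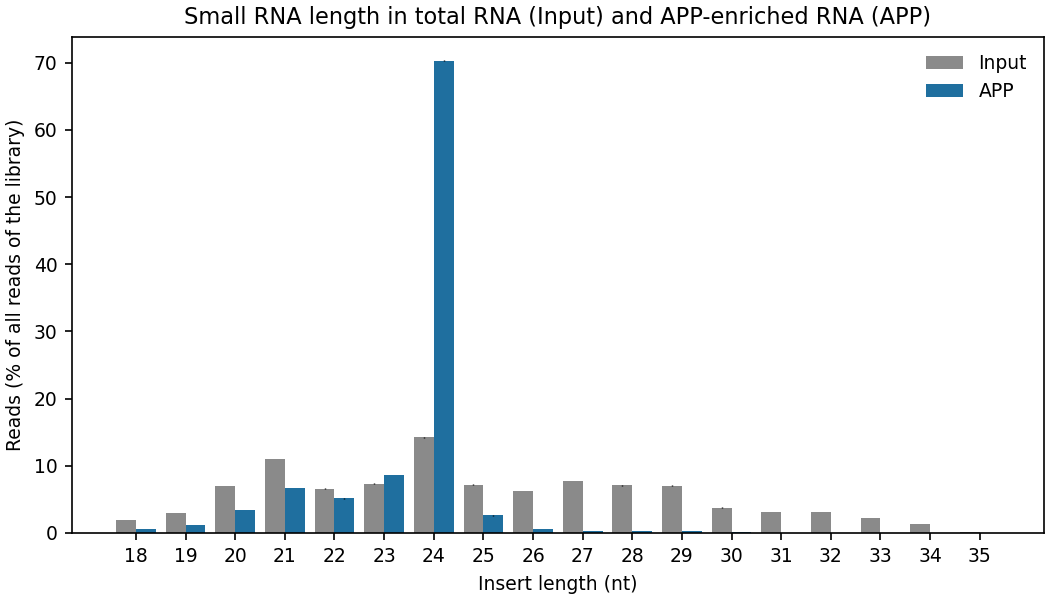
Share of all reads of each library (y axis, percent) at each insert length up to 35 nt (x axis, nt), for Input (grey) and APP (blue), 1 library each. Error bars are exact 95% binomial intervals and are mostly narrower than the line. The APP bar at 24 nt reaches 70.3%, against 14.2% in Input, and Input keeps reads at every length from 25 to 34 nt.

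The authors' deposited table of lengths covered 18 to 28 nt and held the same read counts as the sequence files at all 11 lengths. On that base, the authors' deposited table gave 17.96% of Input and 70.6% of APP at 24 nt, and 13.9% and 6.71% at 21 nt. Part of the 24-nt difference went with the loss of other RNA: among genome-matched reads that shared no base with structural RNA, 24-nt reads made up 39.7% of Input and 75.0% of APP, a log2 ratio of 0.92 (0.91 to 0.92). In the same reads the 21-nt shares were 11.4% and 6.07%, a log2 ratio of -0.91, and the direction at 23 nt turned, with 12.5% of Input and 8.04% of APP (log2 ratio -0.64, -0.65 to -0.63). The ratio of 24-nt to 21-nt reads in that set was 3.49 in Input and 12.4 in APP, 3.54-fold higher in APP. Shares of a whole depend on each other, so a higher 24-nt share by itself lowers the shares of other lengths. Per all reads instead, the 21-nt and 23-nt reads of that set had log2 ratios of 1.25 and 1.52.

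Fragments of annotated structural RNA were nearly removed from APP. Annotated rRNA, tRNA, snRNA and snoRNA together took 32.4% of Input reads (32.35 to 32.47%) and 1.03% of APP reads (1.02 to 1.04%), a 31.3-fold lower share in APP (log2 ratio -4.97, -4.99 to -4.95). tRNA fragments were lowest relative to Input, at 20.7% and 0.102% of reads, a log2 ratio of -7.67 (-7.72 to -7.62). In Input, 85.4% of the tRNA reads were longer than 24 nt. Annotated rRNA went from 9.99% to 0.787% (log2 ratio -3.67), and snRNA or snoRNA from 1.68% to 0.145% (-3.54). Reads of the 25S rRNA region, which the annotation does not list as rRNA, took 24.5% of Input and 3.00% of APP (log2 ratio -3.03, -3.04 to -3.02). Reads of 5S rRNA, also not listed, went the other way, with 0.224% of Input and 0.299% of APP (log2 ratio 0.41, 0.37 to 0.46). With the 25S and 5S rRNA added, structural RNA made up 57.1% of Input and 4.34% of APP.

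Most APP reads instead matched loci annotated as pseudogenes or places between genes, which in this genome hold many transposons. Pseudogene reads made up 6.10% of Input and 46.4% of APP, 7.62-fold higher in APP (log2 ratio 2.93, 2.92 to 2.94). Reads between genes took 3.76% and 18.4% (log2 ratio 2.29, 2.28 to 2.30). Among reads free of structural RNA the log2 ratios of these 2 classes were 0.78 and 0.25. Reads in protein-coding genes took 4.65% and 8.39% (log2 ratio 0.85, 0.84 to 0.86, but -1.28 among reads free of structural RNA), and within them 24-nt reads had a log2 ratio of 2.54 while reads of other lengths had one of -0.78 (0.39 and -2.91 among reads free of structural RNA). In the pseudogene class, 64.5% of Input reads and 82.4% of APP reads were 24 nt long. MIR genes, which encode miRNA precursors, held 1.48% of Input reads and 4.19% of APP reads, 2.84-fold higher in APP (log2 ratio 1.51, 1.49 to 1.52), but were lower in APP among reads free of structural RNA, at 8.08% and 5.14% (log2 ratio -0.65, -0.67 to -0.64). Reads without an exact genome match made up 21.2% of Input and 13.8% of APP.

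**Figure D2:**
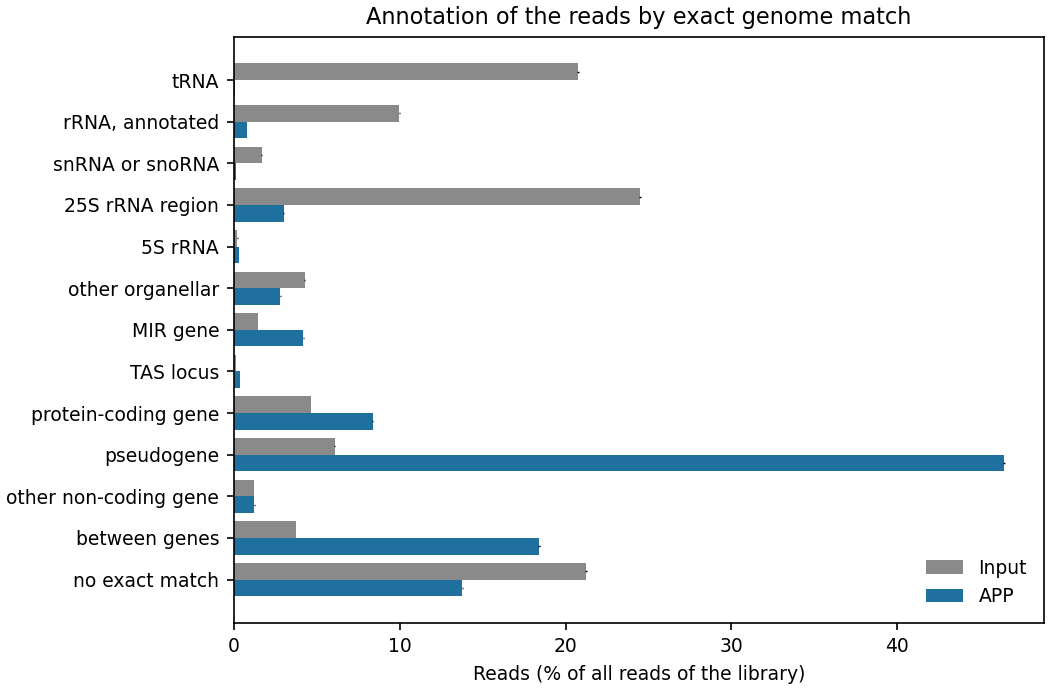
Share of all reads of each library (x axis, percent) in each annotation class (y axis) by exact genome match, for Input (grey) and APP (blue), 1 library each, with exact 95% binomial intervals. tRNA and the 25S rRNA region hold 20.7% and 24.5% of Input but 0.102% and 3.00% of APP, and pseudogenes hold 6.10% of Input and 46.4% of APP.

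At single loci the direction mostly followed the class. Of 644 annotated loci with at least 1000 reads over both libraries (MIR and TAS genes left out), 501 were higher in APP in rpm, and 486 per read free of structural RNA. The first count held 443 of 444 pseudogenes and 44 of 59 protein-coding genes (35 per read free of structural RNA), whereas all 97 tRNA genes and all 10 rRNA genes were lower in APP. The minimum was on reads summed over both libraries, so loci tended to pass it through the library where their class was high. The tRNA class held 544849 reads in Input and 3461 in APP, and the pseudogene class 160208 and 1577901. The counts for these classes therefore largely repeat the class ratios. The highest ratio belonged to AT4G19270, a gene for an uncharacterized protein (TAIR10.1 chromosome 4, 10537555 to 10538021), at 34.5 rpm in Input and 949.9 rpm in APP (log2 ratio 4.78, 4.48 to 5.09), although 67.6% of its APP reads also matched elsewhere. AT3G22142, which encodes a member of the protease inhibitor, seed storage and lipid transfer protein family (chromosome 3, 7803492 to 7808046), rose from 130.2 to 2143 rpm (log2 ratio 4.04, 3.88 to 4.20). AT3G22125 (7803338 to 7808056) spans that stretch on the other strand and had 343 reads in Input and 7294 in APP (log2 ratio 4.04), against 342 and 7280 for AT3G22142. The pseudogene AT3G43000 (chromosome 3, 15044566 to 15046814) had 36.7 rpm in Input and 516.3 rpm in APP (log2 ratio 3.81, 3.51 to 4.12). At these 4 loci between 84.0 and 91.8% of APP reads were 24 nt long. The lowest ratios belonged to tRNA genes. AT3G05525, for tRNA-Glu (chromosome 3, 1601338 to 1601409), had 4533 rpm in Input and 3 reads in APP (log2 ratio -12.33, -14.60 to -10.78). AT1G03515, AT5G15815 and AT5G21378, copies of tRNA-Asp that share all their reads, each had 579.5 rpm in Input and 0.287 rpm in APP (log2 ratio -10.94, -16.25 to -8.46). These values are equal parts of the same reads and so a single measurement. The interval treats a divided count of 0.976 reads in APP as a whole count and is only nominal.

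The first base of a small RNA is known to sort it between plant Argonautes: AGO1 favours U, and AGO2 and the AGO4 clade favour A. Among 24-nt reads, A stood first in 44.3% of Input reads (44.14 to 44.46%) and 76.2% of APP reads (76.19 to 76.30%), a log2 ratio of 0.78. Among 21-nt reads, U stood first in 16.7% of Input reads (16.57 to 16.84%) and 59.1% of APP reads (58.92 to 59.32%), a log2 ratio of 1.82. In Input, 62.9% of 21-nt reads began with C, against 13.7% in APP. Without reads that shared a base with structural RNA, the 24-nt share of A was 63.8% in Input and 77.1% in APP, and the 21-nt share of U was 47.3% and 64.7%. In that set the share of A at 22 nt was 28.8% in Input and 65.1% in APP, and at 23 nt it was 34.1% and 65.2%. The 21-nt difference rested on a few abundant sequences. With each distinct sequence counted once it came to a log2 ratio of 0.09 (25.1% and 26.7%), and among distinct sequences free of structural RNA it turned, with 25.8% in Input and 24.2% in APP, while A rose from 31.4 to 51.5%. Without the 10 most abundant sequences of either library the log2 ratio of U was 0.46 (28.3% and 38.9%). For A at 24 nt the corresponding log2 ratios were 0.29 and 0.70.

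**Figure D3:**
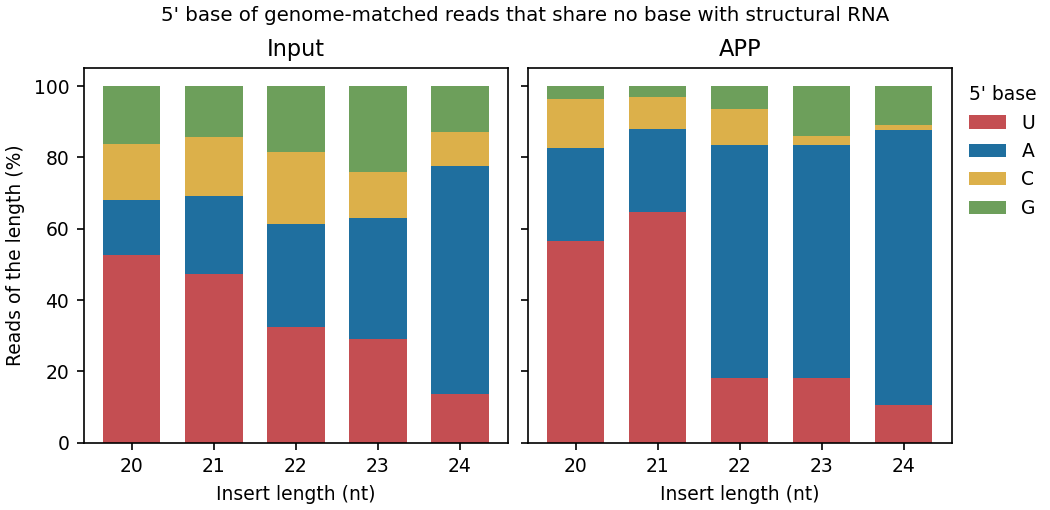
Share of reads (y axis, percent) that begin with U, A, C or G at each length from 20 to 24 nt (x axis, nt) among genome-matched reads that share no base with structural RNA, for Input and APP, 1 library each. A leads at 22, 23 and 24 nt in APP, with 65.1%, 65.2% and 77.1%, and U leads at 20 and 21 nt in both libraries.

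The guide strands of known miRNAs took a higher share of APP than of Input, mainly through miR159a. Of a list of 72 guides, 43 were detected in at least 1 library. Together they made up 0.693% of Input reads (0.683 to 0.703%) and 2.51% of APP reads (2.49 to 2.53%), a 3.62-fold higher share in APP (log2 ratio 1.86, 1.83 to 1.88). miR159a, which targets MYB transcription factors of the GAMYB type, had 5406 reads in Input and 61132 in APP. Without it the shares were 0.487% and 0.710%, a log2 ratio of 0.54. Relative to genome-matched reads that shared no base with structural RNA the direction turned, with guides at 3.79% of Input and 3.08% of APP (log2 ratio -0.30). The listed star strands, the partners of the guides in the duplex, took 0.0158% of Input (0.0143 to 0.0174%) and 0.0246% of APP (0.0229 to 0.0263%), a log2 ratio of 0.63 (0.46 to 0.81). This rested mainly on miR408-5p, which held 207 of the 416 star reads in Input and 594 of the 835 in APP. The log2 ratio of the stars turned to -1.52 among reads free of structural RNA and to -0.40 among 20 to 24-nt reads. With each distinct sequence counted once it was -0.27, which only compares 11 stars detected in Input with 8 in APP.

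Of the 19 guides with at least 100 reads over both libraries, 12 were higher in APP and 7 lower in rpm, with a median log2 ratio of 0.54. The interval lay above 0 for 11 of them and below 0 for 6. That median stood at percentile 30.1 among 10000 random lists of 19 sequences matched on abundance, drawn from 106 other sequences of 20 to 22 nt, a description of these libraries. The choice of denominator shifted every log2 ratio alike, by -1.03 per 20 to 24-nt reads, by -1.86 per listed guide read and by -2.16 per genome-matched read free of structural RNA. The number of guides higher in APP then came to 6, 6 and 4. The shift per listed guide read mainly reflects miR159a, which held 5406 of 18197 guide reads in Input and 61132 of 85254 in APP. Without miR159a the log2 ratio of the guide share was 0.54, against 1.86 with it.

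A small set of guides was higher in APP under each of these denominators. miR159a (TTTGGATTGAAGGGAGCTCTA, chromosome 1, 27713234 to 27713254, in the MIR159a gene) had 2057 rpm in Input (2003 to 2113) and 17993 rpm in APP (17851 to 18136), a log2 ratio of 3.13 (3.09 to 3.17). Its close relative miR159b-3p (chromosome 1, 6220813 to 6220833, in MIR159b) had 16.7 and 171.9 rpm (log2 ratio 3.36, 2.92 to 3.84). The sequences differ only in the last base, so miR159a reads changed at that base would count as miR159b-3p, which was not tested. The highest ratio belonged to miR162a-3p, which targets the mRNA of the miRNA-processing enzyme DCL1 and matched MIR162a (chromosome 5, 2634936 to 2634956) and MIR162b (7740610 to 7740630). It had 34 reads in Input and 534 in APP, 12.9 and 157.2 rpm (log2 ratio 3.60, 3.10 to 4.15). miR840-5p (chromosome 2, 771492 to 771513, in MIR840) had 14.5 and 119.2 rpm (log2 ratio 3.04, 2.56 to 3.56).

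Other guides were lower in APP under each denominator. miR827 (TTAGATGACCATCAACAAACT, chromosome 3, 22122811 to 22122831, in MIR827), which targets a transcript for an SPX-domain protein in phosphate homeostasis, had 167 reads in Input and 1 in APP, 63.6 and 0.294 rpm (log2 ratio -7.75, -13.07 to -5.26). miR160a-5p, which targets mRNAs of auxin response factors and has identical copies in MIR160a, MIR160b and MIR160c, went from 109 to 16 reads, 41.5 (34.1 to 50.0) and 4.71 rpm (2.69 to 7.65), a log2 ratio of -3.14. miR472-3p (chromosome 1, 4182143 to 4182164), which targets resistance gene mRNAs, went from 186 to 33 reads (log2 ratio -2.87, -3.45 to -2.33). miR172c (chromosome 3, 3599791 to 3599811, and an identical copy in MIR172d), which targets AP2-type transcription factors, went from 231 to 90 reads (log2 ratio -1.73, -2.10 to -1.37). Smaller differences were seen for the star miR398b-5p (log2 ratio -0.96, -1.46 to -0.46), miR161.1 (-0.80, -1.24 to -0.35) and miR398b-3p, a guide against copper/zinc superoxide dismutase mRNA (752.8 and 650.5 rpm, -0.21, -0.30 to -0.12). For miR846-3p (-0.41) the interval of the rpm ratio included 0.

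For a further group of named small RNAs the direction depended on the denominator. miR158a-3p, the most abundant listed guide of Input (TCCCAAATGTAGACAAAGCA, chromosome 3, 3366349 to 3366368, in MIR158a), had 2816 rpm in Input and 4215 rpm in APP. This gave a log2 ratio of 0.58 (0.54 to 0.62) in rpm, but -0.45 per 20 to 24-nt reads and -1.58 per genome-matched reads free of structural RNA. miR403-3p, which targets AGO2 mRNA (chromosome 2, 19415154 to 19415174, in MIR403), had 201.7 and 755.8 rpm (log2 ratio 1.91, 1.77 to 2.04), and -0.25 in reads free of structural RNA. miR166a-3p, the guide family that AGO10 binds and that targets HD-ZIP III transcription factors, matched 7 MIR166 genes and had 12.6 and 50.6 rpm (log2 ratio 2.01, 1.47 to 2.60), and -0.15 in reads free of structural RNA. Likewise turning to negative values under at least 1 of these denominators, miR408-5p had a log2 ratio of 1.15 (0.92 to 1.39), miR158a-5p of 0.63 (0.13 to 1.14), miR396b-5p of 0.57 (0.42 to 0.71) and miR408-3p of 0.24 (0.11 to 0.37). For miR408-3p, which targets mRNAs of copper proteins, sequences with other 3' ends raised the log2 ratio to 1.64, from 1517 and 6130 reads. miR173-5p, the trigger of TAS1 and TAS2 siRNAs, had 65.1 and 78.9 rpm, a log2 ratio of 0.28 whose interval included 0.

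Several guides tied to single Argonautes were too rare to compare. miR390a-5p, the partner of AGO7, had 0 reads in Input, which allows up to 1.14 rpm, and 2 reads in APP. miR165a-3p had 1 read in Input and 0 in APP, which allows up to 0.883 rpm. miR393b-3p, the star strand known as a partner of AGO2, had 1 read in Input and 0 in APP. The listed star sequence that the annotation names miR393a-3p had 15 and 10 reads (log2 ratio -0.96, -2.27 to 0.29). miR168a-5p, which targets AGO1 mRNA, had 19 reads of the exact sequence in Input and 9 in APP (log2 ratio -1.45, -2.78 to -0.24), but with other 3' ends included it had 295 and 345 reads, a log2 ratio of -0.14.

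**Figure D4:**
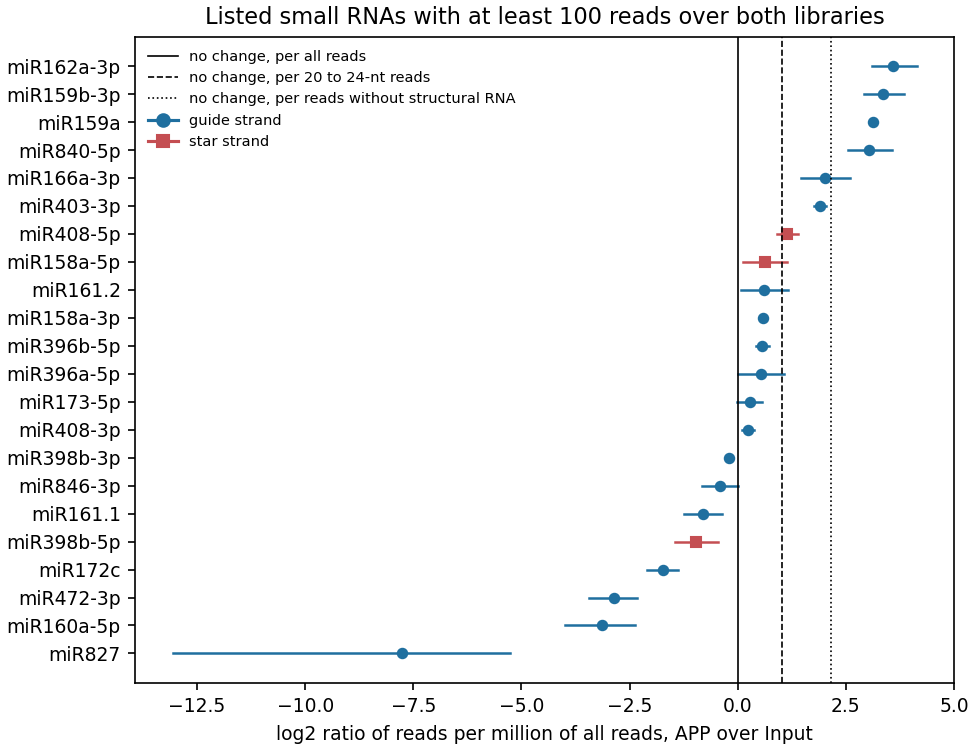
Log2 ratio of rpm, APP over Input (x axis), for each listed guide (circles) and star strand (squares) with at least 100 reads over both libraries (y axis, names), 1 library per group. Horizontal bars are exact 95% counting intervals, and the vertical lines mark no change under each of 3 denominators. The points run from -7.75 for miR827 to 3.60 for miR162a-3p.

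The TAS genes, non-coding transcripts that give rise to trans-acting siRNAs, had a higher share of all reads in APP through TAS1A, TAS1B and TAS1C, and a lower share of the reads free of structural RNA. The 6 TAS loci together took 0.124% of Input reads (0.120 to 0.128%) and 0.379% of APP reads (0.373 to 0.386%), a 3.06-fold higher share (log2 ratio 1.62, 1.56 to 1.67), but among reads free of structural RNA the shares were 0.677% and 0.465% (log2 ratio -0.54, -0.60 to -0.49). TAS1C (AT2G39675, chromosome 2, 16537288 to 16538277) had the most reads, with 533.6 rpm in Input and 2111 rpm in APP (log2 ratio 1.98, 1.90 to 2.07). TAS1B (AT1G50055) had 264.3 and 936.5 rpm (log2 ratio 1.83, 1.71 to 1.95), and TAS1A (AT2G27400) had 149.2 and 372.4 rpm (log2 ratio 1.32, 1.15 to 1.49). TAS2 (AT2G39681) had 283.7 and 365.2 rpm (log2 ratio 0.37, 0.23 to 0.50). Per read free of structural RNA these log2 ratios turned to -0.17 for TAS1C, -0.33 for TAS1B, -0.84 for TAS1A and -1.79 for TAS2, and per 20 to 24-nt reads that of TAS2 turned to -0.67. TAS3 (AT3G17185), whose siRNAs need miR390, had 13 reads in Input and 5 in APP (log2 ratio -1.75, -3.59 to -0.17), and no read matched TAS4 (AT3G25795) in either library. Of the listed siRNAs from these loci, siR255 had 2 and 3 reads, and tasiR-ARF and siR1511 had 0 in both. With each distinct sequence counted once, the log2 ratio of the TAS share was -0.31.

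The lengths of TAS1C reads shifted between the libraries. Reads of 21 nt made up 42.0% of TAS1C reads in Input and 20.9% in APP, and reads of 24 nt made up 21.9% and 55.5%. In rpm, 24-nt reads of TAS1C had a log2 ratio of 3.32 (3.16 to 3.50) and 21-nt reads one of 1.25 (1.12 to 1.38). At TAS2 the corresponding ratios were 2.96 (2.47 to 3.49) and 0.06 (-0.14 to 0.27). Per read free of structural RNA the 24-nt ratios stayed above 0, at 1.17 for TAS1C and 0.80 for TAS2, and the 21-nt ratios fell below 0, at -0.91 and -2.10. These ratios by length count a read in full at each locus that it matches, unlike the percent values above. A 21-nt sequence shared by TAS1A, TAS1B and TAS1C had 53 reads in Input and 533 in APP. It made up 27.2% of the 21-nt APP reads counted at TAS1C, and with divided reads the 21-nt ratio of TAS1C would be lower.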

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

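Of the tests in this part, those on the sequencing cycle, the bait and the transgene vector (2 tests), and the search of unmatched sequences itself, were chosen after the result was seen.

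Sequences without a genome match equalled parts of bacterial cloning plasmids in a list written from memory, a signal outside the comparisons of lengths and loci that stood far above its level in Input. They came to 14.5 rpm in Input (38 reads) and 4362 rpm in APP (14821 reads), and reads of the GST coding sequence, the tag of the bait, numbered 0 in Input and 1436 in APP, at least 370.2-fold higher in APP. The plasmid, GST, adapter and mammalian miRNA sequences could not be checked against a database, and the labels do not name the vector of the bait.

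The tables argue against fragments of the RKD2-GFP transgene vector that the capture did not enrich, since the same cells fed both libraries and the upper 95% bound in Input was 19.9 rpm. They argue against reads from mammalian small RNA libraries as well, because the fold of mammalian miRNAs was 0.0087 of the plasmid fold. That list cannot show reads from libraries of other organisms, such as bacteria, which were not tested. A candidate explanation that stays open is nucleic acid of the bait preparation, made in bacteria, carried into the APP library, which fits the 301.6-fold difference and the GST reads. Argonaute-bound siRNAs of the transgene vector, a biological explanation, also stay open: without GST 30.1% of the plasmid reads in APP were 21 nt long (29.3 to 30.9%), the most frequent length, against 13.0% of the GST reads, which peaked at 20 nt. A single sequence held 41.4% of those 21-nt reads, and the sequence of the transgene vector was not available. The contrast with GST did not hold at each plasmid part. Reads of 21 nt took 38.7% of the ColE1-type origin, where 1 sequence held 79.4% of them, and 24.5% of the lacI part. They took 51.7% of the T7 terminator, where 1 sequence held 99.6% of them, but 5.12% of the tet remnant, which peaked at 25 nt. The strand written in the list held 99.0% of T7 terminator reads of all lengths in APP, 97.2% of tet remnant reads and 86.9% of lacI reads. It held 68.4% of reads of the ColE1-type origin and 13.3% of GST reads. Strand was not part of the test.

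Reads equal to mammalian miRNAs came to 305.6 rpm in Input (803 reads) and 800.0 rpm in APP (2718 reads). Reads of the 5' RNA adapter came to 43.8 rpm in Input (115 reads) and 1358 rpm in APP (4614 reads).

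In both libraries, A was often read as C at position 11, counted from the 5' end. Among 122 abundant sequences of Input the share was 7.63% (7.51 to 7.75%) and among 120 of APP it was 6.73% (6.61 to 6.86%). The tables argue against RNA editing, a modified base or a genome variant, since the same 74 genomic bases read 1 position earlier or later showed 0.0025 of the share seen at position 11. A base-calling error at 1 sequencing cycle stays open and may explain the pattern, as the A-to-C share at position 11 was at least 106.4 times the highest A-to-C share at positions 5 to 10 or 12 to 18, in each library and RNA class. Of other changes, A read as T at position 14 reached 6.67% in Input (0.0377% in APP), but exceeded 1% in 4 of 268 sequences of Input, against 122 of 122 for A to C at position 11.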

How the results depend on the processing

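Alternatives chosen after seeing the data were the ranges of 18 to 28 nt and, for guides, stars and TAS loci, of 20 to 24 nt, both sets of reads without structural RNA, 25S and 5S rRNA and unmatched reads, the added 25S and 5S rRNA, the partial overlaps, all annotated miRNAs, position 11 read as A, and leaving out miR159a. Of 55 alternatives for the 9 shares, 47 kept the direction, 41 of them moved by more than the counting interval, and 8 reversed. No paired analysis was possible because each group held 1 library, and for the same reason there was no library to leave out in turn. At this depth a count of 0 allows up to 1.14 rpm in Input and 0.883 rpm in APP. Of 72 listed guides, 29 had no read in either library, and why was not tested. All values are log2 ratios of APP over Input, and the cause was not tested except where stated.

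With each distinct sequence counted once, the ratios were -0.67 for 21 nt, 1.09 for 24 nt, -1.97 outside 20 to 24 nt, 0.089 for 5' U, 0.29 for 5' A and -2.88 for structural RNA. They reversed to -0.078 for guides, -0.27 for stars and -0.31 for TAS loci. For guides and stars this only compares how many list members were detected, 41 guides in Input with 34 in APP and 11 stars with 8. These counts are few and do not measure abundance. Without the 10 most abundant sequences of either library the ratios were -0.50 for 21 nt, 2.24 for 24 nt, 0.46 for 5' U, 0.70 for 5' A, 0.34 for guides and 1.46 for TAS loci. Over genome-matched reads they were -0.93 for 21 nt, 2.25 for 24 nt, -3.46 outside 20 to 24 nt, 1.73 for guides, -5.10 for structural RNA and 1.49 for TAS loci.

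With annotated structural RNA left out, the ratios were -1.15 for 21 nt, 2.12 for 24 nt and -2.91 outside 20 to 24 nt. With unmatched reads left out as well, they were 1.94 for 5' U and 0.44 for 5' A. Over genome-matched reads not wholly inside structural RNA, 25S or 5S rRNA, the set used first, they were -0.73 for 21 nt, 1.14 for 24 nt and, reversed, -0.063 for guides. Over reads that share no base with it, the set that replaced it after those values had been seen, they were -0.91 for 21 nt, 0.92 for 24 nt, -2.46 outside 20 to 24 nt, 0.45 for 5' U, 0.27 for 5' A and, reversed, -0.30 for guides, -1.52 for stars and -0.54 for TAS loci. From 20 to 24 nt only they were 0.83 for guides, 0.59 for TAS loci and, reversed, -0.40 for stars. From 18 to 28 nt only they were -1.05 for 21 nt and 1.97 for 24 nt. With other 3' ends, guides had 1.77 and stars 0.45. Guides had 1.71 for all annotated miRNAs, 1.88 with position 11 read as A and 0.54 without miR159a. Structural RNA had -3.72 with 25S and 5S rRNA and -4.85 with partial overlaps.

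A new denominator shifts every ratio of a single small RNA by a constant, which by construction is the cause of these reversals. Per listed guide read, a denominator made up mostly of miR159a in APP, the reversed values were -1.28 for miR158a-3p, -1.23 for miR158a-5p and -1.58 for miR173-5p. They were -1.29 for miR396b-5p, -1.62 for miR408-3p and -0.71 for miR408-5p. Per 20 to 24-nt reads they were -0.45, -0.40, -0.75, -0.46 and -0.79 for the first 5 of these. Per read free of structural RNA they were -1.58, -1.53, -1.88, -1.59, -1.92 and -1.01 in the same order, and -0.15 for miR166a-3p and -0.25 for miR403-3p. The other named small RNAs kept their direction under these denominators, and with other 3' ends all 22 did. With a minimum of 10 reads, 21 listed small RNAs were higher in APP, against 14 with 100.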

Other observations

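In this part, the test on a few abundant sequences and the 2 tests on reads that share a base with structural RNA, their read set and bounds included, were chosen after the result was seen.

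A group of small RNAs that share the start TCCGCTGTAGCAC was among the most abundant in both libraries, chosen after its values were seen. It made up 1.29% of Input reads (1.28 to 1.30%) and 2.95% of APP reads (2.93 to 2.97%), a log2 ratio of 1.19 (1.18 to 1.21) that turned to -0.87 among reads free of structural RNA. The 5' ends with the most reads lay outside annotated genes (TAIR10.1), at chromosome 5, 4162131 and 4162279 on the plus strand, and chromosome 1, 6926888 on the minus strand. Both sites on chromosome 5 had the same divided counts, 8723 reads in Input and 30798.5 in APP each, and are not separate measurements. Other sites lay on chromosome 2. Among annotated miRNAs outside the fixed list, also chosen after their values were seen, miR158b (chromosome 1, 20772273 to 20772292) had 1974 reads in Input and 7861 in APP, a log2 ratio of 1.62 (1.55 to 1.69) that falls below 0 per read free of structural RNA, where every ratio shifts by -2.16.

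In several classes of loci that mostly give other products, reads of 24 nt had higher ratios than the rest of their class. In snRNA or snoRNA they did not, at 9.65% of the class in Input and 9.47% in APP. In the 3 classes that follow, 24-nt reads were still lower in APP. At the 25S rRNA region, annotated rRNA and tRNA, 24-nt reads had log2 ratios of -0.73, -2.19 and -5.63, and other lengths had -3.44, -4.51 and -7.94. At 5S rRNA, 24-nt reads had a log2 ratio of 2.66 (2.56 to 2.75), and 85.1% of them began with A in APP against 22.7% in Input, while 5S reads of other lengths had a log2 ratio of -1.50. In plastid and mitochondrial reads that shared no base with structural RNA, 24-nt reads had a log2 ratio of 2.45 per all reads and 0.30 (0.27 to 0.33) per read of that set, and other lengths had -1.25 and -3.41. At TAS1C a single 24-nt sequence, AGAATACGCTATGTTGGACTTAGA (chromosome 2, 16537833 to 16537856), made up 43.0% of the 24-nt reads in APP, with 149 reads in Input and 1712 in APP. Across 1193 windows of 100000 bp, 24-nt counts free of structural RNA in the libraries had a Pearson r of 0.949 on the log2 scale and a Spearman rho of 0.915, a relation across windows, which are not replicates. In these reads APP held 10.2 reads per distinct 24-nt sequence and Input 1.42, and thinned to the 190896 reads of Input, APP would hold 94979 distinct sequences against 134575. Without thinning, 83.8% of these distinct sequences had a single read in Input and 5.21% in APP. How far PCR copies account for this was not tested.

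The higher 24-nt share of APP and its lower 21-nt share were set against the makeup of the libraries. The first set of reads used for this was added once the data had been examined, but its test and bounds were written before its ratios were seen. By these bounds, loss of structural and unmatched RNA was to count as the cause of the 24-nt rise with a log2 ratio below 0.3 once these reads were left out, and as excluded with one above 1. Without unmatched reads and reads wholly inside structural RNA the ratio fell from 2.31 to 1.14, past that upper bound. For 21 nt the bounds set beforehand were 0 or higher for the cause and below -1 for its exclusion, and the ratio of -0.73 lay between them, which left that test undecided.

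The set of reads was then redefined, because tRNA fragments that reach past the annotated gene had stayed in it, and without all reads that share a base with structural RNA the ratios were 0.92 for 24 nt and -0.91 for 21 nt. Neither reaches the earlier bounds of 1 and -1. The bounds were loosened at that point, after these values had been seen, to a counting interval wholly above 0.3 for 24 nt and wholly below 0 for 21 nt, and only by these later bounds do the values argue against lost reads as the whole cause. Lost reads account for much of the 24-nt rise on either set, and for 21 nt their removal made the ratio more negative than the -0.71 of all reads. A higher 24-nt share by itself lowers the 21-nt share, as both are parts of a whole. The lower 21-nt share thus does not show that 21-nt RNA was lost in the capture.

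A few abundant sequences are not the whole cause of the 24-nt rise, because the ratio was 2.24 without the 10 most abundant sequences of either library. With each distinct sequence counted once it was 1.09, just above the bound of 1 for this test, but error variants of abundant sequences count as distinct there. Among distinct sequences free of structural RNA, 134575 of 306647 in Input and 203394 of 293186 in APP were 24 nt long. Capture of Argonaute-bound siRNAs may account for part of it, as the share of 24-nt reads that began with A was 13.6 percentage points higher in APP in the first set of reads and 13.3 in the redefined one. Loss of other degraded RNA from APP would raise that share too and stays open, as does any difference in library preparation, with 1 library per group.

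Reads of 23 nt in APP may in part be 24-nt siRNAs that lack the last base, a hypothesis from their share of 5' A. Of 23-nt reads in the first set, 53.9% in APP equalled the first 23 nt of a 24-nt sequence of that library, little above the 50% set beforehand, and in the redefined set 53.8% did. In the redefined set 37.4% equalled the last 23 nt of one, and in Input the shares were 30.3% and 29.4%. Part of this overlap comes with the density of 24-nt sequences, which was not modelled.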
